A study of Mus musculus with 12 samples.

How the data were processed

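Whole-lung RNA of male C57BL6 mice was measured on 12 Affymetrix Mouse430 2.0 arrays, 3 in each of 4 groups (vehicle, LPS, simvastatin, simvastatin with LPS). Groups were taken from the sample titles, since the labels give 1 description for all 12 samples. An LPS array whose title carries no number was called LPS array 3. The intensity values were signals per probe set as deposited, scaled by the authors to the same trimmed mean on every array; no other normalization and no software is given in the sources used here. The trimmed means of the 12 arrays, with 2% of values left out at each end, were 149.6 to 149.7. Each signal came with a detection call. The series value table held the same values (largest difference 0). The array information files gave no scan dates, and their operator entry differed on LPS array 3 and simvastatin array 1.

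Signals under 1 were set to 1 (0.056% of tested values) and log2 transformed without further normalization. Of 45101 probe sets 64 controls were left out, and 27359 called Present on at least 3 of 12 arrays were tested. Of the 45037 probe sets that are not controls, 34945 carry 1 gene symbol, 932 several and 9160 none. Each of 12943 genes was represented by its tested probe set with the highest mean. Group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated errors (8 residual and 3.45 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were LPS against vehicle, both treatments against simvastatin, simvastatin against vehicle, both treatments against LPS, the average of the last 2, and the difference of the first 2 (interaction). Where a group had no Present call, its array values were raised to the lowest Present signal of the array (0.9 to 3.9) where lower. The fold was then marked with the words at least. This floor is not a confidence limit, and a signal not called Present can lie above it. Where neither group had a Present call no fold was given.

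Gene lists (43, with 721 symbols, of which 4 matched no probe set) were written before the data were examined, as were the groups, the tests, the filter, the threshold, most of the alternatives named below and the rule for named genes. Of these lists 41 had enough tested members. They were tested with camera of limma at a preset correlation of 0.01 between genes and adjusted over the lists of a comparison; an estimated correlation and the rotation test fry were the alternatives. The rule for named genes took, per comparison, the 10 largest rises and falls among genes past the threshold whose groups did not overlap, up to 4 members with the smallest p of each list described, and the 5 genes with the smallest p where fewer than 5 passed. A last part of the rule named 2 genes that are not analysed here. The result of 1 list is not reported here. The slope between the LPS effects was fitted by least squares across genes, with errors from a jackknife over arrays. List scores, the mean log2 signal of the members per array, were tested by exact permutation of the simvastatin label within each LPS state. Alternatives covered normalization, filters, an offset at low signal, variance models, samples in the fit, blocks by replicate number or operator entry, and each array left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

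The method was tested on simulated data, with 200 of 27359 probe sets changed per comparison. Between 2 groups 40% to 56% of 2-fold and 86% to 92% of 4-fold changes were recovered. The average effect gave 76% and 98%, the interaction 10% and 62%. Of the calls 3.12% to 8.20% were false. Of 199 unchanged lists 10 had p below 0.05, which leaves correlated members untested. Arrays were treated as unpaired.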

Results

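Whole-lung RNA from male C57BL6 mice aged 7 to 8 weeks was measured on 12 Affymetrix Mouse430 2.0 arrays, which read each transcript with sets of short oligonucleotide probes. The arrays formed 4 groups of 3: vehicle alone, lipopolysaccharide (LPS), simvastatin, and simvastatin with LPS. LPS, a component of the bacterial outer membrane that provokes acute inflammation, was given into the trachea and the lungs were taken at 24 h. The labels give its dose as 2.5 ug/kg, a unit that was not checked against another source. Simvastatin, a cholesterol-lowering drug that blocks an early step of sterol synthesis, was given at 20 mg/kg in 2 doses over the 48 h before collection. The labels name inflammation and endothelial barrier function as the subjects of the study. Each array gave a signal and a detection call for 45037 probe sets other than controls. The share called Present was 53.2 ± 3.01 (mean ± SD) percent in the vehicle group, 54.8 ± 0.507 with LPS, 55.1 ± 0.603 with simvastatin and 55.1 ± 1.84 with both, with 3 arrays in each group. Vehicle array 1 had the lowest share, 49.7%. The number of arrays limits the precision: the median 95% interval of a difference between 2 groups spanned a factor of 1.36 on either side. P-values measure only the spread between these samples, since the labels do not say which mouse each array came from.

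LPS separated the arrays more than any other factor. The first principal component of the tested probe sets carried 59.7% of the variance and placed all 6 LPS arrays on the opposite side from the 6 arrays without LPS. Pearson correlations across tested probe sets were 0.854 to 0.924 between arrays of different LPS state and 0.947 to 0.984 between arrays of the same group. Arrays that shared the LPS state but differed in simvastatin had correlations of 0.949 to 0.981, so groups with and without simvastatin were not told apart by overall similarity. The second component (8.73%) set vehicle array 1 apart with a score of 61.2, and the third (7.27%) set simvastatin plus LPS array 2 apart with a score of 63.7. The ratio of signal at the 3' end to that at the 5' end of the Gapdh control, a measure of RNA integrity, moved with LPS: it was 1.23 ± 0.107 (SD) with vehicle, 1.22 ± 0.13 with simvastatin, 0.947 ± 0.0321 with LPS and 0.918 ± 0.112 with both. The same ratio for actin was 1.59 ± 0.141, 1.4 ± 0.0134, 1.17 ± 0.0183 and 1.18 ± 0.0329 in that order. Below, vehicle array 1 and simvastatin plus LPS array 2 are the outlying arrays, and blocks are by number in the titles (without LPS array 3, whose title has none), number in the signal headers, or operator entry.

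**Figure D1:**
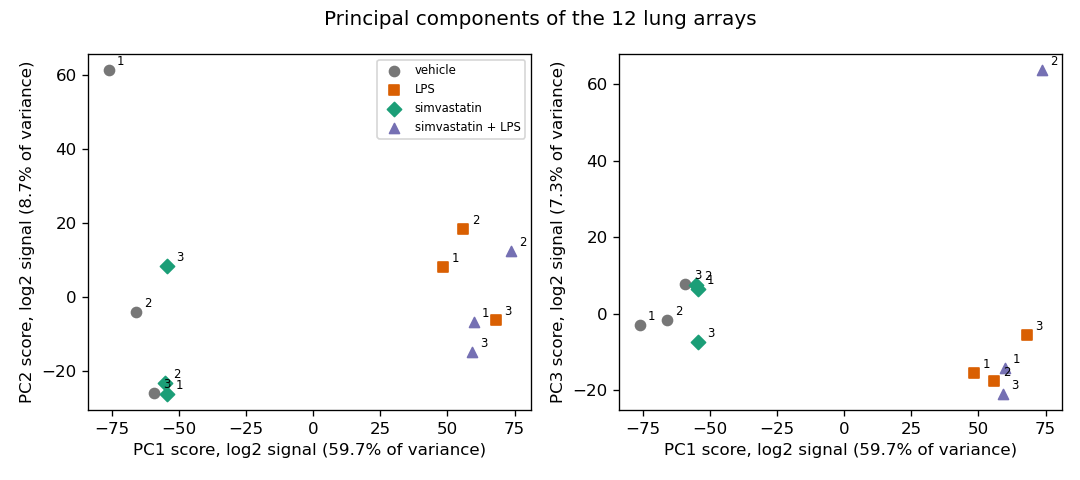
Scores of the 12 arrays on the first 3 principal components of log2 signal, each point an array labelled with its replicate number. LPS and no-LPS arrays lie apart on the first component (59.7% of variance), vehicle array 1 scores 61.2 on the second and simvastatin plus LPS array 2 scores 63.7 on the third.

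The comparison of LPS with vehicle shows which lung transcripts differed 24 h after intratracheal LPS. Higher RNA was called for 28 of 32 cytokines and chemokines, 14 of 17 NF-kB feedback genes and 10 of 12 leukocyte adhesion genes. Of 18 monocyte and macrophage markers 10 rose and 2 fell. Interferon-response genes, acute-phase genes and neutrophil markers ranked higher, with adjusted p = 0.286, 0.155 and 0.107 with an estimated correlation. Markers of ciliated cells, airway secretory cells, smooth muscle and heart muscle ranked lower, with adjusted p = 0.338, 0.46, 0.317 and 0.317 with an estimated correlation. The RNA integrity ratios of Gapdh and actin moved with the same groups. In total 8890 of 27359 probe sets passed the threshold (limma, adjusted p under 0.05), 3816 higher and 5074 lower, and 1544 of the higher and 1931 of the lower differed by at least 2-fold. They stood for 4535 of 12943 genes, 1810 higher and 2725 lower. The median log2 fold change of all tested probe sets was -0.099.

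Acod1 (probe set 1427381_at), which encodes the itaconate-producing enzyme of activated macrophages, was at least 192-fold higher, and its log2 fold change was 7.6 ± 1.04 (SE, as for all log2 fold changes that follow). The chemokine Ccl3 (1419561_at) was at least 186-fold higher, Ccl20 at least 77.6-fold and Cxcl9 at least 58-fold. The words at least mark genes not called Present on any array of the lower group, here vehicle, whose low values were raised to a floor. They give no limit for the spread between arrays. The neutrophil attractants Cxcl3, Cxcl2 and Cxcl5 rose 96-fold, 64.8-fold and 55.1-fold. Csf2, which encodes the growth factor GM-CSF, rose at least 48.2-fold, the C-type lectin gene Clec4e 44.3-fold and the niacin receptor gene Hcar2 at least 44.1-fold. Among the largest falls, the carboxylesterase Ces1f was at least 34.1-fold lower, the methyltransferase Gnmt at least 21.3-fold, the acetyl-CoA carboxylase Acacb at least 14.9-fold, Acoxl 12.8-fold and the aldehyde oxidase Aox3 9.84-fold. Tmem35a (at least 18.2-fold), Snai2 (16.4-fold), Azgp1 (at least 11.5-fold) and the calcium pump gene Atp2b2 (9.88-fold) were lower too. With an offset of 16 the log2 fold changes of Ces1f, Gnmt, Tmem35a and Acacb went from -5.5, -4.41, -4.19 and -3.9 to -2.83, -2.06, -2.18 and -2.49.

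Among the gene lists, 28 of 32 tested cytokines and chemokines rose and 0 fell, and 28 rose when adjusted over the list alone. Their mean log2 fold change was 3.55 (camera adjusted p = 7.66e-19, or adjusted p = 0.0192 with an estimated correlation), and 2.28 with Present calls on all 12 arrays. Ccl2, the main monocyte attractant, rose at least 36.3-fold (5.18 ± 0.27), Il6 at least 43.2-fold (5.43 ± 0.34), Il1b 24.4-fold (4.61 ± 0.32) and the B-cell attractant Cxcl13 12.7-fold (3.67 ± 0.25). Of 17 genes of NF-kB signalling and its feedback, 14 rose over all probe sets and 14 adjusted over the list alone, with a mean of 2.25 (adjusted p = 1.70e-13, or adjusted p = 0.0192 with an estimated correlation). Examples were the ubiquitin-editing inhibitor Tnfaip3 (8.44-fold), Nfkbiz (5.42-fold), Relb (7.41-fold) and Irak3 (15.2-fold). In the adhesion and leukocyte recruitment list, 10 of 12 members rose, 10 adjusted over the list alone, with a mean of 2 (adjusted p = 1.51e-09, or adjusted p = 0.00734 with an estimated correlation). P-selectin, Selp, rose 13.7-fold, and the leukocyte integrin genes Itgam and Itgal rose 12-fold and 4.01-fold. The interferon-response list had 22 of 25 members higher (23 adjusted over the list alone) and a mean of 1.78 (adjusted p = 1.70e-13, or adjusted p = 0.286 with an estimated correlation). Zbp1 was at least 13.3-fold, Irf7 7.34-fold and Bst2 3.48-fold higher.

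Neutrophil and monocyte markers ranked higher, while B-cell, T-cell and natural killer markers did not pass. Of 16 neutrophil markers 13 rose (14 adjusted over the list alone), with a mean log2 fold change of 2.68 (adjusted p = 1.70e-11, or adjusted p = 0.107 with an estimated correlation). The formyl-peptide receptor Fpr2 rose 14.9-fold, Clec4d 23.2-fold, Trem1 at least 7.77-fold and Trem3 6.73-fold. Among 18 monocyte and macrophage markers 10 rose and 2 fell (12 and 2 adjusted over the list alone), with a mean of 1.55 (adjusted p = 7.79e-07, or adjusted p = 0.0192 with an estimated correlation). Ms4a6d rose 13-fold, the Fc receptor gene Fcgr3 6.86-fold, the scavenger receptor gene Msr1 at least 7.41-fold and the LPS co-receptor gene Cd14 6.91-fold. Alveolar macrophage markers as a list did not pass (2 higher and 2 lower of 13, over all probe sets and adjusted over the list alone; mean -0.062, adjusted p = 0.925): Marco, a bacterial scavenger receptor, rose 7.73-fold, while the mannose receptor gene Mrc1 fell 1.5-fold and Pparg 2.7-fold. The log2 fold change of Marco was 2.95, and 1.9 without vehicle array 1 or 1.9 without both outlying arrays. Mrc1 lost its call with the title-number block (-0.55), and Pparg went from -1.43 to -0.87 with an offset of 16.

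In the acute-phase and iron list 13 of 17 members rose and 1 fell (14 and 1 adjusted over the list alone; mean 2.35, adjusted p = 2.82e-09, or adjusted p = 0.155 with an estimated correlation). Serum amyloid A, Saa1, rose 40.8-fold, the zinc transporter gene Slc39a14 11.8-fold and the metalloreductase gene Steap4 8.55-fold. Of 12 complement genes 5 rose, over all probe sets and adjusted over the list alone (mean 0.83, adjusted p = 0.0153, or adjusted p = 0.317 with an estimated correlation). Among them were factor B, Cfb (11.2-fold), and the receptor gene C5ar1 (9.5-fold). In the coagulation and fibrinolysis list 4 of 12 rose and 2 fell by both counts (mean 0.77, adjusted p = 0.0313, or adjusted p = 0.183 with an estimated correlation). Factor X, F10, was 13.7-fold and the urokinase receptor, Plaur, 4.65-fold higher. Oxidative stress genes had 10 higher and 2 lower of 17 by both counts (mean 1.03, adjusted p = 1.34e-04, or adjusted p = 0.317 with an estimated correlation). The NADPH oxidase subunits Ncf1 and Cybb rose 5.54-fold and 5.21-fold, and the glutathione transferase gene Gstm1 fell 2.88-fold. Of 16 immediate-early genes 8 rose and 1 fell by both counts (mean 0.68, adjusted p = 2.95e-04, or adjusted p = 0.233 with an estimated correlation). Myc was 5.53-fold and Junb 3.75-fold higher. Glucocorticoid-response genes had 4 of 12 members higher by both counts (mean 0.70, adjusted p = 0.0228, or adjusted p = 0.503 with an estimated correlation). The list was led by Fkbp5 (4.17-fold) and Angptl4 (5.32-fold). Without vehicle array 1 the mean of this list was 0.52 and its call was lost (adjusted p = 0.112). It was also lost with Present calls on all 12 arrays (0.54), array weights (0.63) or both outlying arrays left out (0.52). The coagulation call was lost with Present calls on all 12 arrays (0.51) or array weights (0.72), and the complement call with array weights (0.77).

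Markers of alveolar type 1 and endothelial cells did not pass, and the other structural lists passed at the preset correlation but not with an estimated one. Ciliated-cell markers had 14 of 17 members lower (15 adjusted over the list alone; mean -1.16, adjusted p = 2.61e-05, or adjusted p = 0.338 with an estimated correlation). Examples were Tppp3 (2.56-fold) and Cdhr3 (3.01-fold). Airway club and goblet cell markers had 8 of 13 lower (9 adjusted over the list alone; mean -0.59, adjusted p = 0.0272, or adjusted p = 0.46 with an estimated correlation). The list had the secreted defence protein gene Bpifa1 2.33-fold and the cytochrome gene Cyp2f2 1.92-fold lower. Alveolar type 2 markers had 6 of 12 lower by both counts (mean -0.46, adjusted p = 0.0313, or adjusted p = 0.322 with an estimated correlation). Among them were the surfactant protein gene Sftpb (1.69-fold), Lpcat1 (1.6-fold) and Hc (3.04-fold). Of 18 fibroblast and smooth muscle markers 9 fell by both counts (mean -0.69, adjusted p = 0.0272, or adjusted p = 0.317 with an estimated correlation). They included smooth muscle myosin, Myh11 (5.14-fold), calponin, Cnn1 (4.26-fold), and Inmt (2.54-fold). Heart muscle markers, which the lung samples carried at high signal, had 13 of 14 lower (14 adjusted over the list alone; mean -1.64, adjusted p = 1.08e-06, or adjusted p = 0.317 with an estimated correlation). Examples were the cardiac myosin genes Myh6 (3.21-fold) and Myl7 (3.3-fold) and Csrp3 (5.33-fold). The RNA integrity ratios given above moved with the same groups. The club list lost its call without vehicle array 1 (mean -0.38), LPS array 1 (-0.53) or LPS array 2 (-0.50), and its mean was -0.38 with both outlying arrays left out. The type 2 list lost it without LPS array 1 (-0.45) or LPS array 2 (-0.39) and with quantile normalization (-0.28), which took Sftpb from -0.76 to -0.47 and Cyp2f2 from -0.94 to -0.55. The fibroblast list lost it without vehicle array 3 (-0.58).

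Cholesterol synthesis genes had 9 higher and 1 lower of 19 (9 and 2 adjusted over the list alone; mean 0.23, adjusted p = 0.0171, or adjusted p = 0.317 with an estimated correlation). Sc5d was 1.8-fold and Fdps 1.84-fold higher. The cholesterol call was lost with array weights (0.14). Fdps went from 0.88 to 0.55 with array weights and lost its call with the title-number block (0.63). Fatty acid synthesis genes had 1 higher and 5 lower of 13 (1 and 6 adjusted over the list alone; mean -0.46, adjusted p = 0.0377, or adjusted p = 0.362 with an estimated correlation). The lipogenic regulator Srebf1 was 2.1-fold and the acyltransferase gene Gpam 2.09-fold lower. The call of the fatty acid list was lost without vehicle array 2 (-0.44), vehicle array 3 (-0.48) or LPS array 2 (-0.41), or with _x_at probe sets left out (-0.41).

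The endothelial, matrix and circadian lists did not pass. Endothelial markers had 1 higher and 4 lower of 19 by both counts (mean -0.23, adjusted p = 0.772): the VEGF receptor gene Kdr fell 2.32-fold and Aplnr 4.04-fold, and Robo4 rose 1.81-fold (0.86 ± 0.24, adjusted p = 0.0189). Robo4 lost its call without vehicle array 1 (0.71), vehicle array 2 (0.81), LPS array 2 (0.84) or LPS array 3 (0.76), or with the title-number block (0.72), which also leaves out LPS array 3. Endothelial genes known to respond to statins had 2 higher and 1 lower of 11 (4 and 1 adjusted over the list alone; adjusted p = 0.0657). In the matrix remodelling list 9 of 19 rose and 4 fell by both counts (adjusted p = 0.131), and the protease inhibitor gene Timp1 rose 18.4-fold. Circadian clock genes had 2 higher and 6 lower of 14 (2 and 7 adjusted over the list alone; adjusted p = 0.224), with the clock output gene Dbp 4.22-fold and Per3 3.34-fold lower.

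The other lists described here did not pass in vehicle-treated mice, and their counts over all probe sets follow. Members higher and lower were 1 and 5 of 18 for the cell cycle (adjusted p = 0.925; Bub1, a mitotic checkpoint kinase gene near the lower end of the signal range, at least 7.62-fold lower, with a log2 fold change of -3.28, or -0.79 with an offset of 16), 2 and 0 of 13 for heat shock and unfolded protein genes (0.0743), and 3 and 0 of 11 for prostaglandin and leukotriene genes (0.178). They were 3 and 1 of 11 for MHC class II antigen presentation (adjusted p = 0.415; the co-stimulator gene Cd80 2.88-fold higher), 1 and 0 of 8 for T cells (0.772; the homing receptor gene Ccr7 3.71-fold higher), 0 and 1 of 10 for natural killer cells (0.925; Klra8 2.79-fold lower), 1 and 3 of 11 for B cells (0.281) and 0 and 1 of 6 for plasma cells (0.925). Alveolar type 1 markers had 0 and 1 of 10 (adjusted p = 0.714), erythroid markers 0 and 0 of 4 (0.925), platelet markers 0 and 0 of 6 (0.925), thymus and lymph node markers 0 and 1 of 4 (0.818), and adipose, thyroid and esophagus markers 0 and 2 of 5 (0.158). Bile acid and lipid transport genes had 3 and 1 of 13 (adjusted p = 0.819), ribosomal protein genes 0 and 0 of 10 (0.925) and mitochondrial respiratory genes 1 and 0 of 19 (0.819). Mast cell, basophil and eosinophil markers and liver markers had 2 tested members each and were not tested as lists. The mean and the median differed in sign for the T-cell list (0.11 and -0.11) and the bile acid list (0.0032 and -0.026). The natural killer, platelet, ribosomal and mitochondrial lists had means below 0 (-0.02, -0.083, -0.039 and -0.0039) but ranked slightly above other genes.

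In simvastatin-treated mice the comparison of both treatments with simvastatin alone shows the response to LPS under the drug. The cytokine, NF-kB feedback, adhesion and monocyte lists ranked higher, each also with an estimated correlation (adjusted p = 0.0231, 0.0231, 0.0122 and 0.0285). Interferon-response genes and neutrophil markers ranked higher (adjusted p = 0.226 and 0.0844 with an estimated correlation). Ciliated, heart muscle and B-cell markers ranked lower (adjusted p = 0.488, 0.509 and 0.488 with an estimated correlation), and the RNA integrity ratios moved with the same groups. In total 8774 probe sets passed (limma), 3605 higher and 5169 lower, with 1404 and 1851 of them changed at least 2-fold. They stood for 4239 genes, 1694 higher and 2545 lower. Ccl3 was at least 93.1-fold higher (6.54 ± 0.83), Acod1 at least 82.8-fold (6.37 ± 1.04), Cxcl3 37.6-fold and Cxcl2 31.6-fold. The acute-phase genes Orm1 and Saa1 rose 34.5-fold and 32.3-fold, Tnf at least 33.2-fold, the G-protein regulator Rgs16 at least 32.8-fold, the interleukin-1 antagonist Il1rn 30.6-fold and the inhibitory receptor gene Siglece at least 29-fold. Among the largest falls were Snai2 (14.2-fold), Tmem35a (at least 14-fold), the proton pump subunit Atp6v1b1 (at least 10.8-fold), Acoxl (10.3-fold), Krtap17-1 (at least 9.37-fold), the retinol acyltransferase Lrat (8.94-fold), the tight junction gene Cldn8 (at least 8.86-fold), Ecm2 (at least 6.91-fold), Acacb (at least 8.21-fold) and Zfp750 (8.09-fold). Without simvastatin plus LPS array 2 the log2 fold changes of Cldn8, Ecm2 and Acacb went from -3.15, -3.14 and -3.04 to -2, -1.84 and -2, and to -2, -1.84 and -2 without both outlying arrays. That of Zfp750 went from -3.02 to -1.85 without simvastatin plus LPS array 1, and its call was lost without simvastatin array 3 (-2.88, adjusted p = 0.0503). Ecm2 lost its call when only the 2 groups were fitted (-3.14, adjusted p = 0.0501), and went to -1.91 with array weights. With an offset of 16 Cldn8, Ecm2, Acacb and Zfp750 went to -2.09, -1.52, -1.81 and -1.57. The same offset took Siglece, Tmem35a and Atp6v1b1 from 4.86, -3.81 and -3.43 to 3.11, -2.06 and -1.58.

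In this comparison the cytokine and chemokine list had 27 higher and 0 lower of 32 (27 and 0 adjusted over the list alone; mean 3.06, adjusted p = 1.49e-18, or adjusted p = 0.0231 with an estimated correlation). Its members Ccl2, Il6, Il1b and Cxcl13 rose at least 23.4-fold, 21.7-fold, 15-fold and 11.1-fold. NF-kB feedback genes had 13 higher and 1 lower of 17 (13 and 1 adjusted over the list alone; mean 2.03, adjusted p = 5.97e-13, or adjusted p = 0.0231 with an estimated correlation). Adhesion genes had 9 higher and 0 lower of 12 (10 and 0 adjusted over the list alone; mean 1.63, adjusted p = 2.24e-08, or adjusted p = 0.0122 with an estimated correlation). Monocyte and macrophage markers had 10 higher and 1 lower of 18 (10 and 1 adjusted over the list alone; mean 1.27, adjusted p = 4.78e-06, or adjusted p = 0.0285 with an estimated correlation). These were the 4 lists whose calls held with an estimated correlation, in vehicle-treated and in simvastatin-treated mice. Interferon-response genes had 24 higher and 0 lower of 25 (24 and 0 adjusted over the list alone; mean 1.89, adjusted p = 3.32e-15, or adjusted p = 0.226 with an estimated correlation). Acute-phase genes had 14 higher and 0 lower of 17 (15 and 0 adjusted over the list alone; mean 2.5, adjusted p = 1.01e-12, or adjusted p = 0.0823 with an estimated correlation). Neutrophil markers had 13 higher and 0 lower of 16 (13 and 0 adjusted over the list alone; mean 2.39, adjusted p = 7.33e-12, or adjusted p = 0.0844 with an estimated correlation). The complement list had 4 higher and 0 lower of 12 (5 and 0 adjusted over the list alone; mean 0.72, adjusted p = 0.0147, or adjusted p = 0.297 with an estimated correlation). The coagulation list had 5 higher and 1 lower of 12 (6 and 1 adjusted over the list alone; mean 0.74, adjusted p = 0.0183, or adjusted p = 0.12 with an estimated correlation). The oxidative stress list had 10 higher and 2 lower of 17 (11 and 2 adjusted over the list alone; mean 1.03, adjusted p = 2.65e-05, or adjusted p = 0.297 with an estimated correlation). Immediate-early genes had 7 higher and 0 lower of 16 (7 and 0 adjusted over the list alone; mean 0.65, adjusted p = 3.37e-04, or adjusted p = 0.226 with an estimated correlation). Glucocorticoid-response genes had 4 higher and 0 lower of 12 (4 and 0 adjusted over the list alone; mean 0.77, adjusted p = 0.0066, or adjusted p = 0.488 with an estimated correlation). Cholesterol synthesis genes had 6 higher and 0 lower of 19 (6 and 1 adjusted over the list alone; mean 0.18, adjusted p = 0.0421, or adjusted p = 0.39 with an estimated correlation). Statin-responsive endothelial genes had 4 higher and 1 lower of 11 (5 and 1 adjusted over the list alone; mean 0.48, adjusted p = 0.0421, or adjusted p = 0.359 with an estimated correlation). Heat shock genes had 3 higher and 0 lower of 13 (1 and 0 adjusted over the list alone; mean 0.36, adjusted p = 0.0421, or adjusted p = 0.297 with an estimated correlation). The coagulation call was lost with quantile normalization (0.71) or Present calls on all 12 arrays (0.51). The calls of the last 3 lists were lost for cholesterol synthesis with quantile normalization (0.19), array weights (0.17), _x_at probe sets left out (0.18) or both outlying arrays left out (0.20), for statin-responsive genes with quantile normalization (0.42), array weights (0.45), _x_at probe sets left out (0.48) or the operator block (0.45), and for heat shock genes with quantile normalization (0.37), Present calls on all 12 arrays (0.30) or _x_at probe sets left out (0.35).

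Ciliated markers had 0 higher and 12 lower of 17 (0 and 14 adjusted over the list alone; mean -0.92, adjusted p = 6.39e-04, or adjusted p = 0.488 with an estimated correlation) after LPS in simvastatin-treated mice. Heart muscle markers had 0 higher and 9 lower of 14 (0 and 12 adjusted over the list alone; mean -0.87, adjusted p = 0.00394, or adjusted p = 0.509 with an estimated correlation). Fatty acid synthesis genes had 1 higher and 5 lower of 13 (1 and 7 adjusted over the list alone; mean -0.41, adjusted p = 0.0483, or adjusted p = 0.454 with an estimated correlation). B-cell markers had 1 higher and 7 lower of 11 (1 and 8 adjusted over the list alone; mean -0.56, adjusted p = 0.0306, or adjusted p = 0.488 with an estimated correlation): the complement receptor gene Cr2 fell 2.28-fold, Cd22 1.93-fold and the antigen receptor component Cd79a 2.12-fold, while the low-affinity IgE receptor gene Fcer2a rose 2.42-fold. The B-cell call was lost without simvastatin array 1 (-0.46), simvastatin array 3 (-0.49) or simvastatin plus LPS array 2 (-0.46), or with quantile normalization (-0.45), array weights (-0.41), the operator block (-0.48) or both outlying arrays left out (-0.46). Without simvastatin plus LPS array 2 the glucocorticoid list went to 0.49 and lost its call (adjusted p = 0.0721), as it did with both outlying arrays left out (0.49). The cholesterol list lost its call without simvastatin array 2 (0.16), simvastatin array 3 (0.18), simvastatin plus LPS array 2 (0.20) or simvastatin plus LPS array 3 (0.14). The heat shock list lost it without simvastatin array 2 (0.36), simvastatin array 3 (0.35) or simvastatin plus LPS array 1 (0.29), and the statin-responsive list without simvastatin array 3 (0.46). The fatty acid list lost it in 9 of 12 fits with an array left out, all but those without simvastatin array 2 and simvastatin plus LPS arrays 1 and 3, with means from -0.42 to -0.35 and -0.41 without any of the 6 vehicle and LPS arrays. Other settings that ended it were array weights (-0.32), _x_at probe sets left out (-0.36), only the compared groups (-0.39), the title-number block (-0.41), the operator block (-0.37) and both outlying arrays left out (-0.28).

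The 2 LPS responses were compared gene by gene, which asks whether simvastatin scales the response. All 3315 genes called in both arms moved the same way, 1356 higher and 1959 lower, against 237 and 536 expected by chance overlap. Across 12943 genes the LPS effects in the 2 arms, which share no array, correlated with a Pearson coefficient of 0.911 (jackknife SE 0.0269) and a Spearman coefficient of 0.863 (jackknife SE 0.0422). Genes are not independent replicates. The least-squares slope of the effect under simvastatin on that under vehicle was 0.848 (jackknife SE 0.0616). Among genes called in vehicle-treated mice it was 0.855, and in the reverse direction among genes called in simvastatin-treated mice it was 1. Since both effects carry error, which lowers a least-squares slope, a Deming slope was also fitted and gave 0.924 (jackknife SE 0.085), within its error of 1. Without the detection filter the least-squares slope was 0.698.

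**Figure D2:**
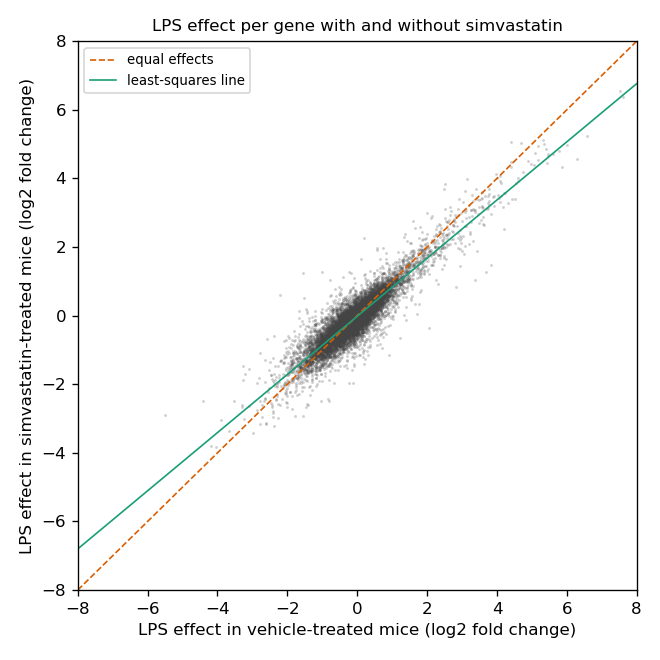
LPS log2 fold change per gene in simvastatin-treated mice (vertical axis) against that in vehicle-treated mice (horizontal axis), each point a gene, with a dashed line of equal effects and a solid least-squares line. The slope of the solid line is 0.848 and the correlation across 12943 genes is 0.911.

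The comparison of simvastatin with vehicle asks what the drug does in lungs without LPS. As sets, genes of cholesterol synthesis, the pathway the drug inhibits, ranked slightly higher than other genes, as did cytokine, interferon-response, neutrophil and cell cycle genes, and sets of ciliated, club cell and heart muscle markers ranked lower. No set kept its call with an estimated correlation (adjusted p = 0.562 to 0.754), and no single named gene passed. The actin ratio of RNA integrity moved with the same groups (at least 1.48 with vehicle, at most 1.41 with simvastatin). With limma 1 of 27359 probe sets passed. It was 1444556_at, which has no gene symbol, was not called Present on any of the 6 arrays and is given no fold (adjusted p = 0.0448). None of the 12943 genes passed. At an unadjusted p under 0.05 there were 1008 probe sets, against 1368 expected by chance. The single call ended when vehicle array 1 or 2, LPS array 1 or 3, simvastatin array 1 or 3, or simvastatin plus LPS array 2 or 3 was left out, each giving a count of 0, and the count was 2 without vehicle array 3.

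The 5 genes with the smallest p in lungs without LPS included the amino acid transporter gene Slc7a5, which was not called Present on any array of either group (unadjusted p = 3.22e-04, adjusted p = 1), Vstm2b (-1.23 ± 0.27), the Nogo receptor gene Rtn4r (at least 2.33-fold higher, not called Present on any vehicle array), the cilium gene Tctn1 (-0.65 ± 0.14) and the DNA repair gene Rad23b (0.53 ± 0.12), all with an adjusted p of 1. Cholesterol synthesis genes had 16 of 19 members above 0, and the mean log2 fold change was 0.13 (adjusted p = 0.00466, or adjusted p = 0.562 with an estimated correlation). The sterol carrier gene Stard4 stood at 0.41 ± 0.12, Idi1 at 0.32 ± 0.15, Cyp51 at 0.40 ± 0.20 and Mvd at 0.26 ± 0.16; 0 members passed, over all probe sets or adjusted over the list alone. The cholesterol call was lost with array weights (0.076) or the operator block (0.10), and without vehicle array 3 (0.10). The cytokine list (24 of 32 members above 0, mean 0.35, adjusted p = 0.00312, or adjusted p = 0.562 with an estimated correlation) included Il33 at 0.54 ± 0.23 and Il1b at 0.66 ± 0.32. Its call was lost with Present calls on all 12 arrays (0.21), and the mean was 0.20 with an offset of 16, 0.55 with array weights and 0.67 with both outlying arrays left out. The NF-kB feedback list (12 of 17 members above 0, mean 0.21, adjusted p = 0.0141, or adjusted p = 0.562 with an estimated correlation) ranked higher, and its call was lost with Present calls on all 12 arrays (0.14) or _x_at probe sets left out (0.17). So did the interferon list (22 of 25 members above 0, mean 0.25, adjusted p = 9.23e-04, or adjusted p = 0.754 with an estimated correlation). Psmb9 stood at 0.35 ± 0.23 and Iigp1 at 0.39 ± 0.25. Neutrophil markers (14 of 16 members above 0, mean 0.35, adjusted p = 9.23e-04, or adjusted p = 0.562 with an estimated correlation) included Csf3r at 0.87 ± 0.32, Fpr2 at 0.55 ± 0.24 and S100a8 at 0.71 ± 0.34, and the mean was 0.65 with array weights. Cell cycle genes (16 of 18 members above 0, mean 0.24, adjusted p = 0.00466, or adjusted p = 0.754 with an estimated correlation) included Rrm1 at 0.42 ± 0.17 and Cdc6 at 1.07 ± 0.48, and the call was lost with array weights (0.12) or both outlying arrays left out (0.13). The last of the higher lists was that of endothelial markers (16 of 19 members above 0, mean 0.20, adjusted p = 0.0141, or adjusted p = 0.754 with an estimated correlation), whose call was lost with the operator block (0.15) or both outlying arrays left out (-0.046). The endothelial nitric oxide synthase gene Nos3, which statins are known to raise, stood at 0.34 ± 0.19 (unadjusted p = 0.0972) in a statin-responsive list that did not pass (adjusted p = 0.2).

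Among the lists that ranked lower without LPS, along with the actin ratio, heart muscle (14 of 14 members below 0, mean -0.60, adjusted p = 1.38e-09, or adjusted p = 0.562 with an estimated correlation) had Myh6 at -0.74 ± 0.26 and Nppa at -0.80 ± 0.34, and a mean of -0.26 with array weights and -0.28 with both outlying arrays left out. Ciliated cells (17 of 17 members below 0, mean -0.28, adjusted p = 9.23e-04, or adjusted p = 0.754 with an estimated correlation) had Cdhr3 at -0.63 ± 0.22 and Tekt4 at -0.42 ± 0.21. Club and goblet cells (12 of 13 members below 0, mean -0.30, adjusted p = 0.00312, or adjusted p = 0.583 with an estimated correlation) had Bpifa1 at -0.50 ± 0.19 and Scgb1a1 at -0.36 ± 0.18. Circadian clock genes (10 of 14 members below 0, mean -0.16, adjusted p = 0.0341, or adjusted p = 0.562 with an estimated correlation) had Dbp at -0.91 ± 0.36 and Per3 at -0.43 ± 0.20. Adipose, thyroid and esophagus markers (4 of 5 members below 0, mean -0.35, adjusted p = 0.0305, or adjusted p = 0.562 with an estimated correlation) also ranked lower. Mitochondrial respiratory genes (16 of 19 members below 0, mean -0.10, adjusted p = 0.0228, or adjusted p = 0.754 with an estimated correlation) completed the group. No member of any list passed adjusted over the list alone. Calls were lost for the club list with quantile normalization (-0.16) or both outlying arrays left out (-0.087), the ciliated list with both outlying arrays left out (-0.057) and the circadian list with no detection filter (-0.16) or array weights (-0.20). They were lost for the adipose list with no detection filter (-0.14), array weights (-0.35), only the compared groups (-0.30), the header-number block (-0.35) or both outlying arrays left out (-0.26), and for the mitochondrial list with no detection filter (-0.10), array weights (-0.044) or both outlying arrays left out (-0.024). Single arrays carried much of this. Without vehicle array 1 the club (-0.087), ciliated (-0.057), mitochondrial (-0.024), adipose (-0.26) and cell cycle (0.13) lists lost their calls, the endothelial mean turned to -0.046, the heart muscle mean was -0.28 and the cytokine mean 0.67. Without vehicle array 2 the cytokine (0.19), NF-kB (0.20), circadian (-0.13), neutrophil (0.22) and adipose (-0.32) lists lost theirs. Without vehicle array 3 the cytokine (0.21), NF-kB (0.19) and circadian (-0.14) lists lost theirs, and the cell cycle (0.37), endothelial (0.40) and ciliated (-0.52) means grew. Leaving out simvastatin array 1 ended the endothelial (0.12) and adipose (-0.30) calls and moved the neutrophil and club means to 0.19 and -0.19. Leaving out simvastatin array 2 ended the endothelial (0.10) and mitochondrial (-0.076) calls and moved the interferon, cell cycle and cytokine means to 0.15, 0.39 and 0.53. Leaving out simvastatin array 3 ended the cytokine (0.25), NF-kB (0.17), cell cycle (0.018), circadian (-0.13) and adipose (-0.31) calls and moved the neutrophil, endothelial and club means to 0.55, 0.36 and -0.48.

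Under LPS, where the comparison asks whether the drug alters the inflamed lung, no probe set passed between simvastatin plus LPS and LPS alone (limma, 0 of 27359; 1144 at an unadjusted p under 0.05, against 1368 expected by chance). Differences in inflammatory mediators did not pass. Il6 stood at -0.61 ± 0.34 and the interferon-induced chemokine gene Cxcl9 at -1.27 ± 0.67, and the cytokine list did not pass (mean -0.14, adjusted p = 0.357). As sets, adhesion, MHC class II and T-cell genes ranked lower and interferon-response, cell cycle, ribosomal, club cell and statin-responsive endothelial genes ranked higher, none with an estimated correlation (adjusted p = 0.603 to 0.73). The 5 genes with the smallest p were Sphkap, not called Present on any array of either group (unadjusted p = 8.25e-05), Ctxn2 (-0.97 ± 0.18), the LPS-deacylating enzyme gene Aoah (-2.41 ± 0.46, near the lower end of the signal range), the melanocortin receptor gene Mc3r (-1.28 ± 0.25) and the phosphatase gene Ptpro (-0.74 ± 0.15), each with an adjusted p of 0.997.

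In the LPS-treated groups the interferon list (24 of 25 members above 0, mean 0.36, adjusted p = 4.58e-05, or adjusted p = 0.73 with an estimated correlation) had Ifit1 at 0.79 ± 0.36, Cmpk2 at 0.76 ± 0.39 and Irgm1 at 0.41 ± 0.20. Without simvastatin plus LPS array 2 its mean was -0.019. The call was also lost with array weights (0.16) or both outlying arrays left out (-0.0092), and the mean was 0.54 with the title-number block. MHC class II genes (9 of 11 members below 0, mean -0.31, adjusted p = 0.00102, or adjusted p = 0.603 with an estimated correlation) had H2-Ob at -0.70 ± 0.24 and the class II transactivator Ciita at -0.32 ± 0.12, and the mean was -0.19 without the same array and -0.19 with both outlying arrays left out. Array weights ended this call (-0.19). T-cell markers (7 of 8 members below 0, mean -0.30, adjusted p = 0.00904, or adjusted p = 0.603 with an estimated correlation) had Cd3g at -0.46 ± 0.18 and Lat at -0.43 ± 0.18, and the call was lost with Present calls on all 12 arrays (-0.30). Adhesion genes (7 of 12 members below 0, mean -0.23, adjusted p = 0.0468, or adjusted p = 0.603 with an estimated correlation) had Itgal at -0.56 ± 0.18, Itga4 at -0.49 ± 0.19 and Selp at -0.46 ± 0.18. The call was lost without LPS array 2 (-0.21), LPS array 3 (-0.21) or simvastatin plus LPS array 3 (-0.17), or with no detection filter (-0.23), Present calls on all 12 arrays (-0.21), array weights (-0.14), the title-number block (-0.22), the operator block (-0.21) or the header-number block (-0.23). Cell cycle genes (12 of 18 members above 0, mean 0.24, adjusted p = 0.0145, or adjusted p = 0.73 with an estimated correlation) had Ccne1 at 1.94 ± 0.52 and Ccna2 at 0.37 ± 0.19, with 2 members higher adjusted over the list alone. The call was lost without LPS array 2 (0.16) or simvastatin plus LPS array 1 (0.23) or 3 (0.23), or with no detection filter (0.15), Present calls on all 12 arrays (0.054) or the title-number block (0.21), and the mean was 0.12 with an offset of 16. Ribosomal protein genes (10 of 10 members above 0, mean 0.14, adjusted p = 0.0102, or adjusted p = 0.73 with an estimated correlation) had Rpl8 at 0.25 ± 0.14 and Rplp0 at 0.21 ± 0.15. The call was lost without LPS array 2 (0.11) or simvastatin plus LPS array 2 (0.081), or with quantile normalization (0.014) or both outlying arrays left out (0.081). Club cell markers (10 of 13 members above 0, mean 0.19, adjusted p = 0.0278, or adjusted p = 0.73 with an estimated correlation) had Bpifa1 at 0.47 ± 0.19 and Scgb3a1 at 0.35 ± 0.15. The call was lost without LPS array 1 (0.13) or 2 (0.10) or simvastatin plus LPS array 1 (0.13) or 3 (0.11), and the mean was 0.35 without LPS array 3 and 0.34 without simvastatin plus LPS array 2. The club call was also lost with quantile normalization (0.15) or Present calls on all 12 arrays (0.16), and the mean was 0.40 with array weights, 0.32 with the title-number block and 0.34 with both outlying arrays left out. The statin-responsive list (9 of 11 members above 0, mean 0.18, adjusted p = 0.0468, or adjusted p = 0.73 with an estimated correlation) had the haem oxygenase gene Hmox1 at 0.54 ± 0.30 and Nos3 at 0.24 ± 0.19. Its call was lost without LPS array 1 (0.18) or 3 (0.14) and without each simvastatin plus LPS array (0.19, 0.16 and 0.20), or with quantile normalization (0.13), no detection filter (0.18), Present calls on all 12 arrays (0.18), array weights (0.15), the title-number block (0.12), the operator block (0.15) or both outlying arrays left out (0.16). Cholesterol synthesis genes did not pass (mean 0.082, adjusted p = 0.145), with Msmo1 at 0.37 ± 0.19, Hmgcs1 at 0.29 ± 0.16 and Fdps at 0.40 ± 0.22. Without LPS array 3 the list was called (0.13). Traf1, a signalling adaptor of the NF-kB list, stood at -0.62 ± 0.17 (unadjusted p = 0.00341).

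The drug effect was also averaged over both LPS states, which sets 6 arrays against 6. As sets, cholesterol synthesis, interferon-response and cell cycle genes ranked higher and T-cell markers lower, none with an estimated correlation (adjusted p = 0.674, 0.926, 0.926 and 0.674). No probe set passed (limma, 0 of 27359; 1261 at an unadjusted p under 0.05, against 1368 expected by chance). Cholesterol synthesis genes (13 of 19 members above 0, mean 0.11, adjusted p = 0.00498, or adjusted p = 0.674 with an estimated correlation) had Stard4 at 0.24 ± 0.086, Mvd at 0.26 ± 0.11, Idi1 at 0.24 ± 0.11 and Cyp51 at 0.30 ± 0.14, and 0 members passed, over all probe sets or adjusted over the list alone. An exact two-sided permutation of the simvastatin label within each LPS state, over 400 assignments, gave the cholesterol score p = 0.04 (0.82 after Benjamini-Hochberg adjustment over 41 lists). The smallest p it allows is 0.005. Interferon genes (25 of 25 members above 0, mean 0.30, adjusted p = 1.25e-07, or adjusted p = 0.926 with an estimated correlation) had Ifit1 at 0.60 ± 0.26 and Cmpk2 at 0.59 ± 0.27, and the mean was 0.11 without simvastatin plus LPS array 2 and 0.11 with both outlying arrays left out. Zbp1 was not called Present on any array without LPS and is given no value (unadjusted p = 0.0595). Cell cycle genes (15 of 18 members above 0, mean 0.24, adjusted p = 2.12e-04, or adjusted p = 0.926 with an estimated correlation) had Ccne1 at 1.26 ± 0.37 and Rrm1 at 0.28 ± 0.12, with 2 members higher adjusted over the list alone. This call ended at 0.13 without simvastatin array 3, and the mean was 0.14 with Present calls on all 12 arrays and 0.15 with an offset of 16. Bub1 was not called Present on any LPS array and is given no value (unadjusted p = 0.00408). T-cell markers (7 of 8 members below 0, mean -0.22, adjusted p = 0.00979, or adjusted p = 0.674 with an estimated correlation) had Lat at -0.28 ± 0.13, and the call was lost at -0.15 without vehicle array 3 and with quantile normalization (-0.14) or no detection filter (-0.19). The 5 genes with the smallest p were Sphkap, not called Present on any LPS array and given no value (unadjusted p = 1.17e-04), Gprasp2 and Vstm2b, not called Present on any simvastatin plus LPS array and given no value (unadjusted p = 6.97e-04 and 8.46e-04), Ctxn2 (-0.69 ± 0.12) and the collagen-binding integrin gene Itga2 (-0.45 ± 0.10), each with an adjusted p of 0.958. Dbp stood at -0.73 ± 0.25 (unadjusted p = 0.0147) in a circadian list that did not pass (adjusted p = 0.411).

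The remaining lists called on average depended on single arrays and on the settings named. Statin-responsive endothelial genes (10 of 11 members above 0, mean 0.16, adjusted p = 0.0239, or adjusted p = 0.677 with an estimated correlation) had Nos3 at 0.29 ± 0.13. The list lost the call at 0.081 without vehicle array 1, 0.14 without LPS array 3 and 0.15 without simvastatin plus LPS array 2, and with quantile normalization (0.14), array weights (0.11), the title-number block (0.13) or both outlying arrays left out (0.068). Neutrophil markers (11 of 16 members above 0, mean 0.21, adjusted p = 0.0252, or adjusted p = 0.937 with an estimated correlation) lost it at 0.14 without vehicle array 2, 0.20 without vehicle array 3, 0.20 without LPS array 3, 0.13 without simvastatin array 1 and 0.079 without simvastatin plus LPS array 2, and with quantile normalization (0.20) or no detection filter (0.17). Endothelial markers (15 of 19 members above 0, mean 0.11, adjusted p = 0.0282, or adjusted p = 0.937 with an estimated correlation) turned to -0.011 without vehicle array 1. They lost the call at 0.088 without LPS array 2, 0.072 without simvastatin array 1, 0.064 without simvastatin array 2, 0.089 without simvastatin plus LPS array 1 and 0.077 without simvastatin plus LPS array 3, and with quantile normalization (0.10), the title-number block (0.10) or both outlying arrays left out (0.044). Their mean was 0.21 without vehicle array 3 and 0.19 without simvastatin array 3. Ciliated markers (15 of 17 members below 0, mean -0.16, adjusted p = 0.0394, or adjusted p = 0.937 with an estimated correlation) lost it at -0.052 without vehicle array 1, -0.16 without vehicle array 2, -0.16 without LPS array 1, -0.15 without LPS array 2, -0.18 without LPS array 3, -0.16 without simvastatin array 1, -0.13 without simvastatin array 2 and -0.063 without simvastatin plus LPS array 2. Their mean was -0.28 without vehicle array 3. The ciliated call was also lost with no detection filter (-0.16), array weights (-0.10), _x_at probe sets left out (-0.17), the title-number block (-0.16), the operator block (-0.16) or both outlying arrays left out (0.049). Erythroid markers (4 of 4 members above 0, mean 0.43, adjusted p = 0.0318, or adjusted p = 0.674 with an estimated correlation) lost it at 0.31 without vehicle array 1, 0.38 without vehicle array 2, 0.42 without LPS array 1, 0.32 without LPS array 2, 0.38 without simvastatin array 1, 0.41 without simvastatin array 3, 0.43 without simvastatin plus LPS array 2 and 0.38 without simvastatin plus LPS array 3. It was lost as well with no detection filter (-0.16), array weights (0.48), _x_at probe sets left out (0.44) or both outlying arrays left out (0.32). Heart muscle markers (14 of 14 members below 0, mean -0.21, adjusted p = 0.00995, or adjusted p = 0.937 with an estimated correlation) lost it at -0.05 without vehicle array 1, -0.16 without LPS array 1, -0.13 without simvastatin array 1 and -0.17 without simvastatin plus LPS array 3. Their mean was -0.33 without vehicle array 2. The heart muscle call was also lost with no detection filter (-0.17), array weights (-0.055) or both outlying arrays left out (-0.066). Across 12943 genes the drug effects with and without LPS correlated weakly (Pearson coefficient 0.112, Spearman coefficient 0.109), and 53.8% of genes had the same sign in both states.

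The interaction is the LPS effect under simvastatin minus that under vehicle. Called sets below 0 were cytokine, adhesion, MHC class II, neutrophil and B-cell genes. Those above 0 were heart muscle, club cell, ciliated, adipose, ribosomal and mitochondrial genes. Heart muscle, club and ciliated markers fell less with LPS under the drug, and B-cell markers further. No set kept its call with an estimated correlation (adjusted p = 0.223 to 0.772), and with limma 0 of 27359 probe sets passed (894 at an unadjusted p under 0.05, against 1368 expected by chance; smallest adjusted p = 0.262). The 5 genes with the smallest p were the glycosyltransferase gene Pomgnt2 (0.87 ± 0.20), Slc7a5, not called Present on any array without LPS and given no value (unadjusted p = 0.00152), the substance P precursor gene Tac1 (2.79 ± 0.68), the translation termination factor gene Gspt2 (0.75 ± 0.19) and Rtn4r, not called Present on any vehicle array and given no value (unadjusted p = 0.0019), each with an adjusted p of 1. Cytokines and chemokines (26 of 32 members below 0, mean -0.49, adjusted p = 0.00264, or adjusted p = 0.512 with an estimated correlation) included Il6, Ccl2 and Ccl4, which were not called Present on any vehicle array and are given no value (unadjusted p = 0.0616, 0.121 and 0.128). The call was lost at -0.32 without vehicle array 2 and with Present calls on all 12 arrays (-0.23) or the operator block (-0.36). The mean was -0.80 without vehicle array 1 and -0.73 with both outlying arrays left out. Of 32 members 11 were called Present on all 12 arrays, a filter that leaves out members with little signal before LPS. Adhesion genes (12 of 12 members below 0, mean -0.37, adjusted p = 0.00228, or adjusted p = 0.223 with an estimated correlation) included Itgal at -0.69 ± 0.26 and Selp at -0.55 ± 0.26. The exact two-sided permutation over 400 assignments gave p = 0.015 for their score, 0.41 after adjustment over 41 lists, the smallest p of any list. MHC class II genes (10 of 11 members below 0, mean -0.35, adjusted p = 0.00228, or adjusted p = 0.504 with an estimated correlation) had Ciita at -0.46 ± 0.18 and H2-Ob at -0.59 ± 0.34, and a mean of -0.23 without simvastatin plus LPS array 2. The MHC call was lost with array weights (-0.18) or both outlying arrays left out (-0.19). Heart muscle markers (14 of 14 members above 0, mean 0.77, adjusted p = 1.42e-09, or adjusted p = 0.504 with an estimated correlation) had Myh6 at 0.87 ± 0.36 and Nppa at 1.31 ± 0.48, and a mean of 0.45 without vehicle array 1, 0.41 with array weights and 0.42 with both outlying arrays left out. The exact permutation gave p = 0.05 for the heart muscle score (0.512 after adjustment). Club cell markers (10 of 13 members above 0, mean 0.50, adjusted p = 1.42e-04, or adjusted p = 0.504 with an estimated correlation) had Bpifa1 at 0.96 ± 0.27 and Scgb3a1 at 0.65 ± 0.21, with 1 member higher adjusted over the list alone, and a mean of 0.28 without vehicle array 1 and 0.30 with quantile normalization. Traf1 stood at -0.76 ± 0.24 in an NF-kB list that did not pass (adjusted p = 0.0896).

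Neutrophil markers (11 of 16 members below 0, mean -0.29, adjusted p = 0.0195, or adjusted p = 0.705 with an estimated correlation) had Trem1, not called Present on any vehicle array and given no value (unadjusted p = 0.0219). The list lost the interaction call at -0.15 without vehicle array 2, -0.27 without vehicle array 3, -0.13 without simvastatin array 1, -0.24 without simvastatin array 2, -0.19 without simvastatin plus LPS array 1 and -0.14 without simvastatin plus LPS array 3. The neutrophil call was also lost with no detection filter (-0.14), Present calls on all 12 arrays (-0.23), the title-number block (-0.18) or the operator block (-0.14). Their mean was -0.45 without vehicle array 1, -0.49 without simvastatin array 3 and -0.54 without simvastatin plus LPS array 2, and -0.77 with array weights and -0.70 with both outlying arrays left out. B-cell markers (10 of 11 members below 0, mean -0.29, adjusted p = 0.0165, or adjusted p = 0.695 with an estimated correlation) had Cd79a at -0.55 ± 0.35. The list lost the call at -0.22 without LPS array 3, -0.18 without simvastatin array 1, -0.22 without simvastatin array 3 and -0.19 without simvastatin plus LPS array 2, and with no detection filter (-0.24), Present calls on all 12 arrays (-0.24), array weights (-0.11), the operator block (-0.12) or both outlying arrays left out (-0.19). Their mean was -0.47 without simvastatin array 2. Ciliated markers (15 of 17 members above 0, mean 0.23, adjusted p = 0.0117, or adjusted p = 0.772 with an estimated correlation) had Cdhr3 at 0.83 ± 0.31. The list lost the call at 0.011 without vehicle array 1, 0.17 without simvastatin array 2, 0.13 without simvastatin plus LPS array 1 and 0.14 without simvastatin plus LPS array 3. Their mean was 0.47 without vehicle array 3 and 0.44 without simvastatin plus LPS array 2, and 0.42 with array weights. Adipose, thyroid and esophagus markers (4 of 5 members above 0, mean 0.59, adjusted p = 0.0117, or adjusted p = 0.296 with an estimated correlation) had 2 members higher adjusted over the list alone. The call was lost at 0.50 without vehicle array 1 and with no detection filter (0.23) or both outlying arrays left out (0.46). Mitochondrial genes (15 of 19 members above 0, mean 0.12, adjusted p = 0.0225, or adjusted p = 0.772 with an estimated correlation) lost it at 0.045 without vehicle array 1, 0.10 without LPS array 1, 0.092 without LPS array 2, 0.10 without simvastatin array 2 and 0.091 without simvastatin plus LPS array 1, and with quantile normalization (0.039), no detection filter (0.12) or both outlying arrays left out (0.061). Ribosomal protein genes (10 of 10 members above 0, mean 0.24, adjusted p = 0.00141, or adjusted p = 0.504 with an estimated correlation) kept the call in every fit with 1 array left out and lost it with quantile normalization (0.015) or both outlying arrays left out (0.13).

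**Figure D3:**
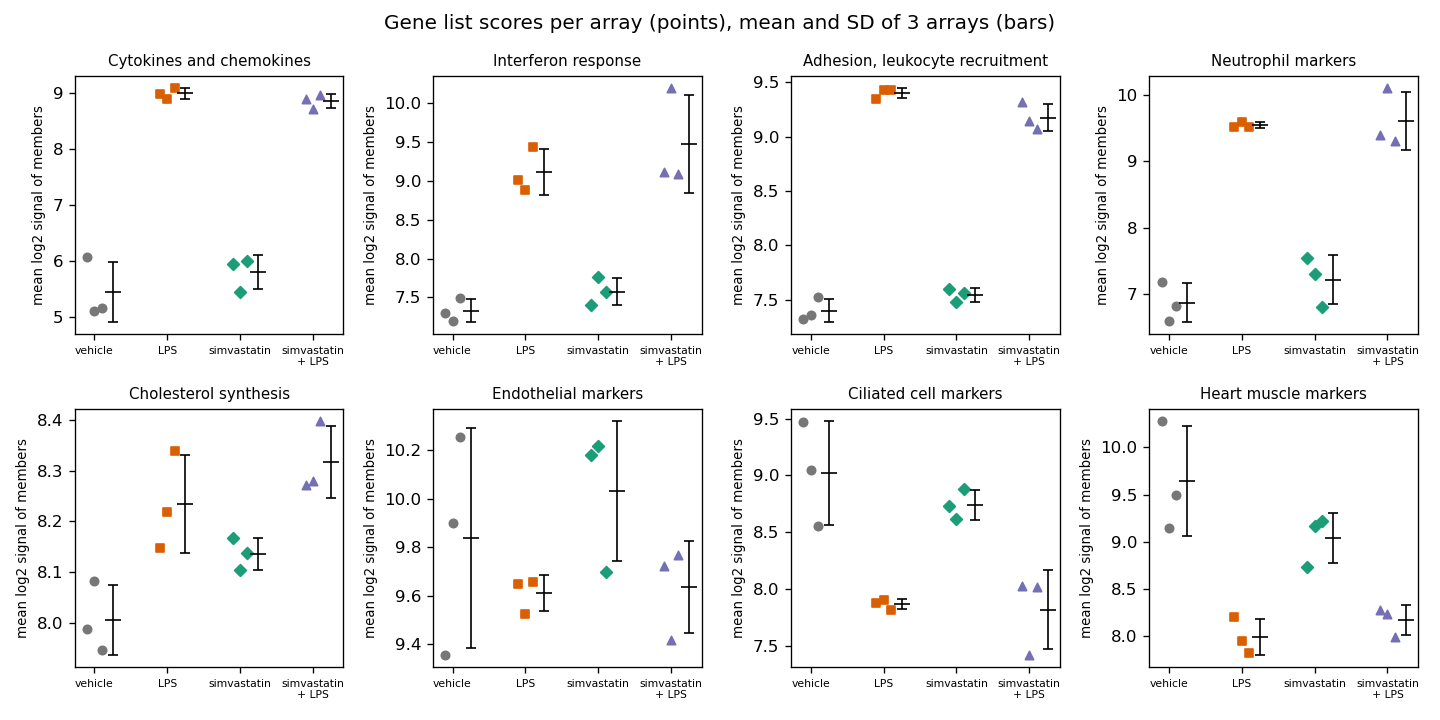
Mean log2 signal of the tested members of 8 gene lists on each of the 12 arrays (points), with the mean and SD of the 3 arrays of each group (bars). LPS arrays lie above the others for cytokines (mean log2 fold change 3.55 in vehicle-treated mice) and below them for heart muscle (-1.64), and simvastatin plus LPS array 2 lies highest for interferon-response genes.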

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

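The tests of the heart muscle pattern and the spread in the cytokine test at low signal were chosen only after the results were seen. The interaction, tested with camera of limma, passed for 11 gene lists. The mean log2 difference was -0.49 for cytokines, -0.37 for adhesion, -0.35 for MHC class II, -0.29 for neutrophil and -0.29 for B-cell lists. It was 0.77 for heart muscle, 0.59 for adipose, 0.50 for club, 0.23 for ciliated, 0.24 for ribosomal and 0.12 for mitochondrial lists. None of the 11 passed with an estimated correlation.

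Real and other splits of the same arrays were compared. For LPS the real one of 10 splits gave 8890 probe sets in vehicle-treated mice, and the highest other 0. In simvastatin-treated mice it gave 8774, and the highest other 1. Other splits put LPS arrays on both sides, so low counts were built in. For simvastatin without LPS 5 of 10 splits reached the real 1 and the highest other gave 7. With 10 splits no share under 0.05 can arise. Under LPS, for the interaction and on average the real count was 0, which all 10, 100 and 100 splits must reach. The highest others were 1, 4 and 4. None of these counts decides on chance.

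The smaller rise of cytokines with simvastatin was weighed against variation that list members share between arrays. An exact permutation over 400 assignments gave p = 0.165 for the score difference, so shared variation remains a candidate explanation. Noise at low signal was tested by adding 16 to every signal, which left a mean difference of -0.33 and the call (adjusted p = 0.00187, in a range of 7.48e-10 to 0.526 over all alternatives). The bound set in advance, 0.5 times the reported difference, was passed by only -0.084 ± 0.063 (SE), too narrow a margin to argue against noise. With Present calls on all 12 arrays the mean was -0.23 and the call was lost (camera adjusted p = 0.526). That filter leaves out members with little signal before LPS. Noise at low signal and an effect of simvastatin on the response stay open.

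Heart muscle markers ranked lower with LPS, but not with an estimated correlation (adjusted p = 0.317 in vehicle-treated and 0.509 in simvastatin-treated mice). Dilution of resident tissue by entering leukocytes was argued against as the only source. The heart muscle score changed by -0.93 ± 0.31 (SE) beyond the alveolar type 1 and endothelial scores. Those fell too (-0.34 ± 0.12 and -0.31 ± 0.17), so dilution in part stays open. Vehicle array 1 alone was argued against, as without it the heart muscle change in vehicle-treated mice was -1.32 ± 0.20. Less heart tissue taken with the lungs of LPS-treated mice stays open. Members' residuals correlated at 0.719 and vehicle arrays scored 10.28, 9.14 and 9.49 (other groups varied less), as varying heart tissue would give. With that correlation the SD of the members' changes (1.16 times their median standard error) cannot tell a common change from a varied response. No table holds the amount of heart tissue, so a response of heart muscle in vessel walls stays open too.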

How the results depend on the processing

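The replicate block by header numbers, the operator block, the fit without both outlying arrays, and the Deming slope were chosen after the data were seen. LPS counts stayed within 1.5 times the reported ones except where given, and the cause was not tested unless the setting itself shows it. Quantile normalization gave 1 probe set for the interaction and 6 lists for the average effect. Without the detection filter simvastatin alone gave 0, lists numbered 5 under LPS, 7 for the interaction and 5 for the average, the slope was 0.698, and erythroid markers reversed to -0.16 on average. Present calls on all 12 arrays gave 0 for simvastatin alone and 3 lists under LPS. Simvastatin alone also gave 0 with an offset of 16, with an intensity trend, with only the compared groups, with either replicate block, and by genes in place of probe sets, where LPS gave 4535 and 4239 genes (fewer items counted). Array weights gave 13417 for LPS in vehicle-treated mice, 8 lists for simvastatin alone and 1 probe set for the interaction. The block by title number, with 11 arrays, gave 5828 for LPS in vehicle-treated mice. Without both outlying arrays the average effect had 1 probe set. Endothelial markers reversed to -0.046 without LPS, interferon genes to -0.0092 under LPS and ciliated markers to 0.049 on average. With an estimated correlation 4 lists passed for each LPS effect and 0 for the other 4 comparisons, and fry gave 0 for those 4. The Deming slope was 0.924.

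With each array left out in turn, counts ranged from 6798 to 9780 for LPS in vehicle-treated mice, 6508 to 9396 in simvastatin-treated mice, 0 to 2 for simvastatin alone, 0 to 0 under LPS, and 0 to 1 for the interaction and for the average. Lists numbered 17 to 20, 14 to 20, 8 to 14, 5 to 10, 9 to 16 and 5 to 12 in that order, and the slope was 0.799 to 0.866. Endothelial markers ranged from -0.046 to 0.40 without LPS and from -0.011 to 0.21 on average, both reversed without vehicle array 1. Interferon genes under LPS ranged from -0.019, reversed without simvastatin plus LPS array 2, to 0.53. Over the other alternatives 913 list results kept direction and call, 191 lost the call, 2 gained it and 4 reversed; with an array left out the numbers were 841, 127, 1 and 3. Named genes kept both in 2557 and lost the call in 4; with an array left out, in 2479 and 5. Robo4, Fdps and Mrc1 lost the call with the block by title number, which also leaves out LPS array 3; without that array alone Robo4 lost it too. Residual correlations of the 15 pairs with the same replicate number were -0.164 to 0.0466, none over 0.1, against -0.178 to 0.172 for 30 other pairs, so the arrays share only a number and not every array correlated best with its own. A block by scan date was not run because the entries are empty. A fit of only the compared groups has no separate form for the interaction and the average, which involve all 4 groups. Signal over background limits what arrays can measure: 27359 of 45037 probe sets passed the filter.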

Other observations

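The tests of interferon genes under LPS and without LPS were chosen only after the results were seen. Several lists had no description in simvastatin-treated mice. After LPS in these mice club and goblet cell markers had a mean log2 fold change of -0.10 (camera adjusted p = 0.723), alveolar type 2 markers -0.39 (0.13) and fibroblast and smooth muscle markers -0.54 (0.0915), none past the threshold. Alveolar type 1 markers stood at -0.43 (0.442), endothelial markers at -0.40 (0.367), MHC class II genes at -0.20 (0.723) and ribosomal protein genes at 0.20 (0.0502). The alveolar type 2 and fibroblast lists passed in vehicle-treated mice, though not with an estimated correlation (adjusted p = 0.322 and 0.317), and their interaction did not pass (0.127 and 0.101).

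Interferon-response genes ranked higher with simvastatin under LPS, without LPS and on average, but not with an estimated correlation (adjusted p = 0.73, 0.754 and 0.926). Under LPS, simvastatin plus LPS array 2 is a candidate source of the difference, since the mean log2 fold change was -0.019 without it and 0.36 with it. Without LPS, variation that the members share between arrays remains open: the adjusted p ranged from 9.37e-06 to 0.754 over all alternatives, and the lowest mean with an array left out was 0.15. On average the exact permutation over 400 assignments gave p = 0.155, where the smallest it can give is 0.005, so shared variation may account for the pattern. An effect of the drug on interferon-response genes stays open.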
